A study of Mus musculus with 20 samples.

How the data were processed

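The series holds 1 dual-colour 180K mouse comparative genomic hybridisation array per tumour, 20 in all. Per the labels, DNA was extracted with DNeasy columns and labelled with a SureTag kit, tumour DNA with Cy5 and non-neoplastic kidney DNA with Cy3, and all arrays have the same dye orientation. Each scanner file was made with Agilent Feature Extraction, version 10.7 per the submitters' processing notes and 10.7.1.1 with protocol CGH_107_Sep09 per the file headers. Each spot's red and green intensity, per the file headers, is a processed signal after background subtraction, spatial detrending and linear dye normalisation. The deposited log ratio is log10 of red over green per the file headers. The deposited value table of the series gives log2 ratios on 174303 spots. Set against each array's own log ratio times the log2 of 10, it differed by at most 6.29e-07, so its scale and direction are those of the scanner files. Its column medians ran from -0.028 to 0.031, so it was not centred by the authors after that step. No column of the files belonged to another sample (0). Probe positions are those of mm9 in the files. No genome of that build was used here, so positions were used as given and sequence context of probes is not analysed here.

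Each array has 180880 spots, of which 174305 are not controls. Control spots and spots with an outlier flag (101 to 685 per array) were left out. Saturated spots (0 to 10 per array) were kept. Log2 of the red over the green processed signal was taken, spots of a probe were averaged and each array was centred on its autosomal median, with no loess or quantile step. This left 170305 probes, 161460 of them on autosomes, 8723 on X and 122 on Y. Chromosomes X and Y were left out of shares, breakpoints, recurrence and list tests. Of the 21138 gene names in the files, 13683 were current symbols, 1546 were older symbols that were updated, and 5909 had no match in the gene table used and kept the file's name. Probes with a gene name numbered 113887, and 56418 had a position alone. List genes with no probe of their own name were read from the probes between their neighbours. These were Bax, Ftl1, Mcl1, Cdkn1b, Cdkn2d, H2ax, Nudt1, Gpx4, Msln, Bap1, Cdkn2b, Stk11, Cdk4, Hras, Terc and the Igl locus, and Bax and Ftl1 share those probes. Ighmbp2 and Iglon5 match the prefixes of the antigen receptor loci but are no part of them and were dropped.

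Each chromosome of each array was segmented by penalised least squares with a penalty of 40 times the noise variance and at least 5 probes per segment, after limiting single probes to 2.5 noise units around a running median of 25 probes. Segments at or above 0.2 were called gained and at or below -0.2 lost. The altered, lost and gained shares are percents of autosomal probes in called segments, and breakpoints are borders between neighbouring segments whose means differ by at least 0.2. A gene's call is the mean of the segmented values of its probes. Recurrence was tested in 2392 bins of 1 Mb with at least 3 probes, by 10000 circular shifts of each tumour's profile along the autosomes, one-sided and with a family-wise p. Each genotype was set against the 7 wild-type tumours by exact two-sided permutation of group means, whose smallest p is 0.00606 for 4 tumours against 7 (330 splits) and 0.0167 for 3 against 7 (120 splits), with Benjamini-Hochberg adjustment over the 4 contrasts. Genes with at least 3 probes (9427, of which 9053 on autosomes, 367 on X and 7 on Y) were tested with limma on mean log2 ratios in 1 fit of all tumours. The 14 gene lists were tested by exact permutation of mean segmented ratios (56 tests) and by shifts for recurrence. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

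The groups, tests, gene lists, rule for named genes and other settings to be tried were fixed before the data were examined. The rule names every engineered gene and tumour suppressor of the lists and up to 6 genes of each other list with the most tumours called, if at least 3. It also names list members or up to 3 genes in the 6 regions with the most tumours (1 per chromosome and direction), up to 5 genes per contrast past the adjusted p, and up to 10 focal segments under 5 Mb with a mean of at least 1 in size. A few genes that the rule names are not reported here. Genes and segments outside it are said to be chosen after their values were seen. The settings so fixed were thresholds of 0.1 and 0.3, penalties of 20 and 80, centring on the mode, normexp background correction with an offset of 50, probes with reference signal well above background on every array (71575 left out), the value table of the series, the wild-type set of the same scan day, scan day, slide or replicate number as a block, other probe minimums, and leaving out each tumour. After seeing the data, settings were added that left out spots in array patches (a local median in a square window of 21 spots over 0.5 from the array median), corrected for probe GC content, left out single tumours in doubt, or removed the shared profile. The shared profile of an array has 2 parts. One is the median of the other 19 arrays at each probe, and the other is that median smoothed by a running median of 101 probes. Both were fitted together to the array by least squares and subtracted. The scale of the unsmoothed part was 0.25 to 1.17. The 2 scales added, which apply to regional changes, were 0.14 to 0.80 on scan day 1 and 0.89 to 1.79 on scan day 2.

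Steps across many genes were tested on simulated data. With 200 of 9427 genes changed, limma recovered 67% of those changed by 0.5 log2 units in the Dmt1Tg contrast, 63% in MutyhKO, 61% in Ogg1KO and 68% in Mth1KO. It recovered 97%, 96%, 98% and 96% of those changed by 1.0, with 5, 7, 8 and 5 false calls. The simulated genes had independent noise with 1 spread per gene and no split by scan day, slide or patch. These rates may therefore not hold in the real data. At the median probe noise of 0.338, segmentation found a loss of 1.0 over 10 probes in 2 of 10 runs and over 35 probes in 10 of 10, and a loss of 0.5 over 35 probes in 4 of 10 and over 100 probes in 10 of 10. The recurrence test found a loss simulated in 15 tumours in 20 of 20 runs, and with no loss simulated 0 of 20 runs passed any bin. Both outcomes were largely set in advance. The runs used random shifts of the real profiles, as the test itself does, and 15 tumours lie above the 9 needed in the real data. The shifted profiles hold no trend shared between tumours, so the runs do not show how the test behaves under 1. The highest correlation between 2 arrays was 0.73 (WT_plain 1 and WT_plain 2) and no file repeated another. Dim spots compress a ratio toward 0 and widen its spread, so a difference at few or dim probes may not have been detectable at this signal.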

Results

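DNA copy number was measured by array comparative genomic hybridisation in 20 peritoneal mesotheliomas, cancers of the lining of the abdominal cavity, that arose in mice injected with crocidolite, an iron-rich form of asbestos. Each animal received 1.5 mg into the peritoneum 2 times, at 6 and 7 weeks of age, 3 mg in total, and was observed for 600 to 700 days. The tumours came from mice of 5 genotypes. There were 7 wild-type tumours in 2 labelled sets (WT_Dmt1, n = 4, and WT_plain, n = 3), 4 from mice with a transgene of Dmt1, the divalent metal transporter that takes iron into cells and whose gene is Slc11a2 (Dmt1Tg), and 3 each from mice lacking Mutyh, Ogg1 or Mth1, whose products act on oxidised guanine. Mutyh is a glycosylase that removes adenine paired with it, Ogg1 is a glycosylase that removes it from DNA, and Mth1, encoded by Nudt1, hydrolyses the oxidised nucleotide before it is built in. Tumour DNA carried Cy5 and non-neoplastic kidney DNA, of the same genotype as the tumour per the labels, carried Cy3, so values are log2 of tumour over kidney and a value above 0 is more DNA in the tumour.

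Each array held 170305 distinct probes of 60 bases at a median spacing of 10.8 kb, with positions on mouse genome build mm9. The spread between neighbouring probes ran from 0.22 log2 units in MutyhKO 1 to 0.53 in WT_Dmt1 1. Between 73.4% (Mth1KO 3) and 97.7% (Ogg1KO 3) of probes were well above background in the kidney channel, and between 91.8% (WT_plain 1) and 99.8% (WT_plain 3) in the tumour channel. The arrays lay on 5 slides scanned on 2 days. WT_Dmt1 filled slide 1 and Dmt1Tg slide 2, both scanned on day 1. Slide 3 held WT_plain 1 to 3 and MutyhKO 1, slide 4 MutyhKO 2 and 3 with Ogg1KO 1 and 2, and slide 5 Ogg1KO 3 with Mth1KO 1 to 3, all scanned on day 2. Slide and group could therefore not be told apart between Dmt1Tg and WT_Dmt1, nor between WT_plain and Ogg1KO or Mth1KO, which shared no slide with it. On WT_plain 1 and WT_plain 2 a patch of the array surface held 6.79% and 4.68% of the spots at median log2 ratios of -2.48 and -3.08. The number of arrays limits the precision of every comparison, and the labels do not say that each tumour came from its own animal, so p-values measure the spread between these samples.

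The 4 engineered genes were examined first, since they bear on the labels. At Slc11a2 (chromosome 15, 100222603 to 100243116) the mean log2 ratio was -0.76 ± 0.13 (SD, n = 4) in Dmt1Tg and -0.85 ± 0.65 (SD, n = 7) in wild type, a difference of 0.09 (SE 0.28, limma adjusted p = 1). Mutyh (chromosome 4, 116480656 to 116490555) stood at -0.15 ± 0.39 (SD, n = 3) in MutyhKO against 0.02 ± 0.61, a difference of -0.18 (SE 0.28, limma adjusted p = 0.868). Ogg1 (chromosome 6, 113280022 to 113280081, 1 probe) stood at -0.86 ± 0.71 (SD, n = 3) in Ogg1KO against -0.93 ± 0.32, a difference of 0.07 (SE 0.59, limma adjusted p = 0.976). Nudt1 had no probe of its own name and was read from 2 probes between its neighbours (chromosome 5, 140801044 to 140806870), at -0.05 ± 0.17 (SD, n = 3) in Mth1KO against -0.11 ± 0.15, a difference of 0.06 (SE 0.15, limma adjusted p = 0.916). Each of the 4 differences lay within the spread between tumours. With a kidney reference of the same genotype, a transgene or deletion present in both channels leaves no difference, and the few probes need not lie in the deleted or inserted part, so these values check no label.

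Dmt1Tg was compared with the 7 wild-type tumours, which served as controls for every genotype and so link the 4 comparisons. In Dmt1Tg 4 a gain covered chromosome 9 from 6969858 to 11562155, with Yap1, the growth-promoting co-activator at the end of the Hippo pathway, Birc2 and Birc3, inhibitors of cell death, and a cluster of matrix metalloproteinase genes. Its mean log2 ratio was 0.74 (SE 0.02 over 336 probes), against 0.08 ± 0.10 (SD) in the other 19 tumours, which ran from -0.18 to 0.31. The same tumour was low at 20 probes in Lpp, a gene for a cell adhesion protein, on chromosome 16 from 24645071 to 24848145, at -0.86 (SE 0.05) against 0.04 ± 0.18 in the other 19. These segments, like the others named for single tumours, were chosen after their values were seen. Save for the focal segments and the kallikrein stretch named below, their borders were found with the shared profile removed. The values are means of the deposited ratios within those borders, so a stretch need not be called from the deposited ratios. Of 9427 genes with at least 3 probes, limma called 0 different between Dmt1Tg and wild type at an adjusted p under 0.05, and 318 had an unadjusted p under 0.05.

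The altered share of the autosomes was 6.87% ± 1.42 (SD, n = 4) in Dmt1Tg and 14.18% ± 15.62 (SD, n = 7) in wild type, a difference of -7.31 percentage points (exact permutation p = 0.461, Benjamini-Hochberg adjusted p = 0.921, two-sided). The lost share was 6.51% ± 1.64 against 9.22% ± 10.12 (difference -2.71, exact p = 0.588, adjusted p = 0.667). The gained share was 0.36% ± 0.27 against 4.96% ± 6.36 (difference -4.6, exact p = 0.182, adjusted p = 0.727). Breakpoints numbered 323 ± 83.8 against 256.9 ± 313.2 (difference 66.1, exact p = 0.685, adjusted p = 0.978). Of the fixed gene lists, iron handling and ferroptosis genes had a mean segmented log2 ratio of -0.111 ± 0.029 in Dmt1Tg and -0.121 ± 0.151 in wild type, a difference of 0.011 (exact p = 0.933, adjusted p = 0.985). Adjusted over the list alone, limma called 1 gene, Vmn2r95, a vomeronasal receptor gene of the copy-variable families on chromosome 17 from 18567006 to 18578976. It was lower in 4 of 4 Dmt1Tg tumours, at a difference of -0.26 (SE 0.07, limma adjusted p = 0.0428 adjusted over the list alone and 1 over all genes). Set against WT_Dmt1 alone, which shares the scan day, the altered share turned to a difference of 4.11 and the lost share to 5.1 (exact p = 0.0571 and 0.0286), and breakpoints to 288.2 (exact p = 0.0286, the smallest that 70 splits allow). With the profile shared by the arrays removed as well these were -1.25, 0.00 and 1.25 (exact p = 0.343, 1 and 0.743). The segmentation penalty grows with array noise. That noise was 0.368 to 0.535 on the WT_Dmt1 arrays and 0.24 to 0.266 on the Dmt1Tg arrays. In simulated profiles a loss of 0.3 over 100 probes was found in 10 of 10 at a noise of 0.218 and in 0 of 10 at 0.535. Noise and group could therefore not be told apart in the comparison with WT_Dmt1.

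MutyhKO differed from wild type in no gene by limma after adjustment (0 of 9427, 866 at an unadjusted p under 0.05), and its clearest losses lay in a single tumour. In MutyhKO 3 the T-cell receptor beta locus was low from 41079318 to 41480704 on chromosome 6, at -0.90 (SE 0.08 over 35 probes), where the other 19 tumours averaged 0.08 and the lowest stood at -0.03. The T-cell receptor alpha locus was low from 54509873 to 54741487 on chromosome 14, at -1.06 (SE 0.11 over 29 probes), where the others averaged 0.11 and the lowest stood at 0.00. These loci are rearranged in T cells, with the DNA between the joined segments removed. Adjusted over the list alone, limma called Mdm4, an inhibitor of p53 (chromosome 1, 134888882 to 134913941), among the oncogenes. It was lower in 3 of 3 MutyhKO tumours at -0.46 ± 0.22 (SD) against 0.10 ± 0.33, a difference of -0.56 (SE 0.16, limma adjusted p = 0.0468 adjusted over the list alone and 0.411 over all genes).

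The altered share in MutyhKO was 13.73% ± 2.48 (SD, n = 3), a difference of -0.45 percentage points from wild type (exact p = 0.983, adjusted p = 0.983, two-sided, smallest p of the 120 splits 0.0167). The lost share was 11.9% ± 2.75 (difference 2.69, exact p = 0.667), the gained share 1.82% ± 0.28 (difference -3.14, exact p = 0.617) and the number of breakpoints 259 ± 96.5 (difference 2.14, exact p = 0.983). Base excision repair genes stood at -0.120 ± 0.041 in MutyhKO against -0.090 ± 0.127 in wild type (difference -0.030, exact p = 0.7). Against the 3 WT_plain tumours of the same scan day the altered share differed by -15.68 and the lost share turned to -7.73 (exact p = 0.1 for each, the smallest that 20 splits allow). In that comparison limma called 331 genes higher and 27 lower in MutyhKO. The largest was 2900092C05Rik on chromosome 7 (13111409 to 13138178), a difference of 1.69 (SE 0.45, limma adjusted p = 0.0455) that was -0.31 (SE 0.17) with the spots in the array patches of WT_plain 1 and 2 left out. Rcbtb1 on chromosome 14 (59820877 to 59848183) stood at -0.05 ± 0.05 in MutyhKO and -1.70 ± 1.1 in WT_plain (difference 1.65, SE 0.36, limma adjusted p = 0.0244, higher in 3 of 3 tumours). With the same spots left out, 12 genes were higher and 6 lower and the Rcbtb1 difference was 0.64 (SE 0.31, limma adjusted p = 0.362). Slide 3 held 1 MutyhKO tumour, so with slide as a fixed term the contrast rested on that tumour alone, and its lack of calls says little.

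In Ogg1KO a difference lay at Slc25a37, the gene of the mitochondrial iron importer mitoferrin, on chromosome 14 from 69863952 to 69899746. It stood at 0.05 ± 0.25 (SD, n = 3) in Ogg1KO and at -0.81 ± 0.41 (SD, n = 7) in wild type, a difference of 0.86 (SE 0.24), higher in 3 of 3 tumours (limma adjusted p = 0.0388 adjusted over the list alone and 0.621 over all genes). The surrounding segment from 69876584 to 70090608, with Entpd4 and Loxl2, stood at 0.73 in Ogg1KO 1 and 0.57 in Ogg1KO 2 and at -1.22 in WT_plain 1 and -1.30 in WT_plain 2, so this stretch varied in both directions between tumours. In Ogg1KO 2 it was not called from the deposited ratios, where its segmented value was -0.02. Mob1b, an adaptor of the Hippo kinases (chromosome 5, 89165482 to 89180540), was lower in 3 of 3 tumours at -0.21 ± 0.11 against 0.09 ± 0.10, a difference of -0.29 (SE 0.08, limma adjusted p = 0.0222 adjusted over the list alone and 0.621 over all genes). In Ogg1KO 1, 13 probes in the Serpina cluster of protease inhibitor genes (chromosome 12, 105048428 to 105263855) stood at 1.08 (SE 0.20) against 0.14 ± 0.40 in the other 19 tumours. Those ran from -0.71 to 0.95, and the segmented value of Ogg1KO 1 in the deposited ratios was 0.31. Whether this high ratio arose in the tumour was not tested. Over all 9427 genes limma called 0, with 723 at an unadjusted p under 0.05.

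The altered share in Ogg1KO was 17.12% ± 8.22 (SD, n = 3), a difference of 2.94 percentage points from wild type (exact p = 0.767, adjusted p = 0.983, two-sided). The lost share was 12.69% ± 3.64 (difference 3.48, exact p = 0.617), the gained share 4.43% ± 5.71 (difference -0.53, exact p = 0.9) and the number of breakpoints 311 ± 165.6 (difference 54.1, exact p = 0.733). Base excision repair genes stood at -0.124 ± 0.023 in Ogg1KO, a difference of -0.034 from wild type (exact p = 0.667). WT_plain and Ogg1KO share no slide, so slide and group could not be told apart between them. Against WT_plain alone the altered share turned to a difference of -12.28 (exact p = 0.3), and limma called 237 genes higher and 13 lower. With the spots in the array patches left out these became 0 higher and 3 lower, all of the Skint cluster on chromosome 4, a copy-variable family of skin T-cell selection genes. Skint6 differed by -0.83 (SE 0.09, limma adjusted p = 0.000175), Skint4 by -0.95 and Skint3 by -1.14, and at each the 3 Ogg1KO tumours lay below the 3 WT_plain tumours. These genes, and the Skint genes named for Mth1KO, were chosen after their values were seen.

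Mth1KO 3 carried a loss of 29 probes with Dis3l2, an RNA exonuclease gene, and Alpi, an alkaline phosphatase gene, on chromosome 1 from 88677867 to 88994963. It stood at -0.67 (SE 0.09) against 0.12 ± 0.11 (SD) in the other 19 tumours. The Slc25a37 stretch of chromosome 14 stood at -1.23 in Mth1KO 2 and -1.23 in Mth1KO 3. No list gene was called in Mth1KO adjusted over the list alone, and limma called 0 of 9427 genes, with 874 at an unadjusted p under 0.05. Large fragile-site genes, which are very long and break under replication stress, stood at 0.151 ± 0.044 (SD, n = 3) in Mth1KO and 0.079 ± 0.070 (SD, n = 7) in wild type, a difference of 0.072 with the lowest p of the 56 tests of lists (exact p = 0.15, adjusted p = 0.952). With the shared profile removed it turned to -0.024 (exact p = 0.0167, adjusted p = 0.233). Base excision repair genes stood at -0.164 ± 0.081, a difference of -0.074 (exact p = 0.383, adjusted p = 0.952).

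The altered share in Mth1KO was 23.26% ± 11.4 (SD, n = 3), a difference of 9.08 percentage points from wild type (exact p = 0.45, adjusted p = 0.921, two-sided). The lost share was 14.43% ± 7.03 (difference 5.21, exact p = 0.45), the gained share 8.83% ± 4.86 (difference 3.87, exact p = 0.433) and the number of breakpoints 393.3 ± 132 (difference 136.5, exact p = 0.467). WT_plain and Mth1KO lay on different slides, so slide and group could not be told apart between them either. Against WT_plain alone the altered share turned to a difference of -6.14 (exact p = 0.5), and limma called 235 genes higher and 14 lower. With the spots in the array patches left out these became 0 higher and 4 lower, Skint3, Skint4, Skint6 and Skint9, with Skint6 at a difference of -0.80 (SE 0.09, limma adjusted p = 0.000293, lower in 3 of 3 tumours). In no genotype did the altered, lost or gained share or the breakpoints pass the test against the 7 wild-type tumours.

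**Figure D1:**
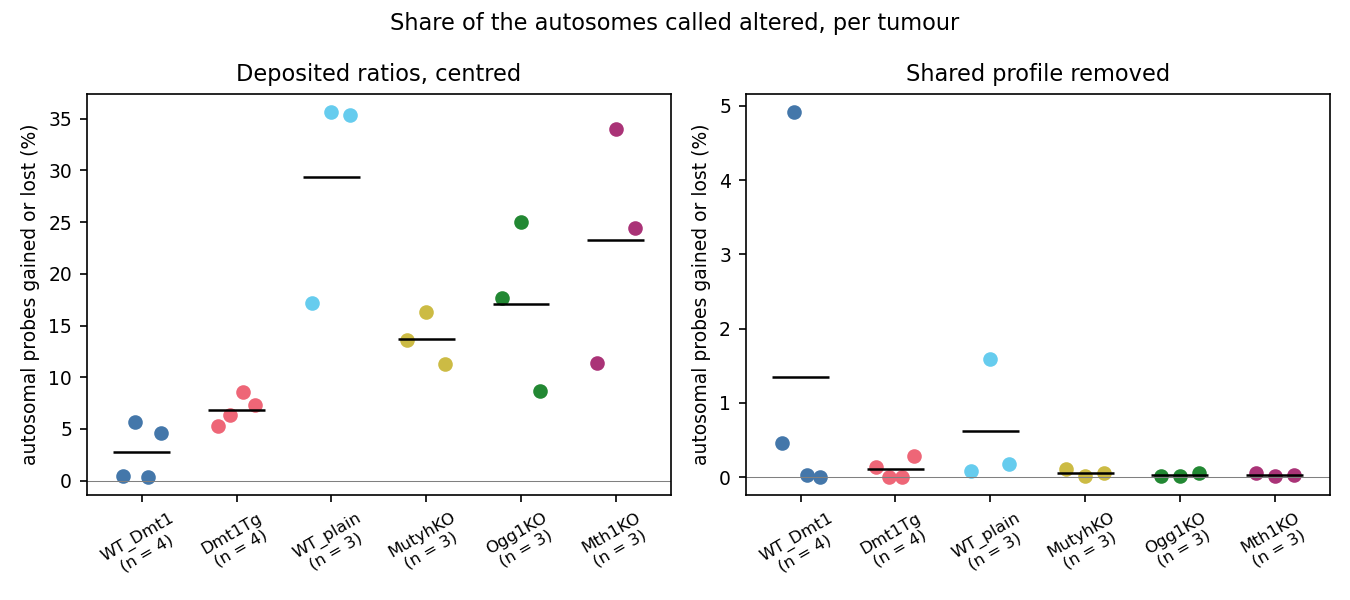
Each point is 1 tumour and each short line a group mean; the vertical axis is the percent of autosomal probes in segments called gained or lost, from the deposited ratios on the left and with the profile shared by the arrays removed on the right. On the left WT_Dmt1 spans 0.33% to 5.63% and WT_plain 17.18% to 35.68%, and on the right the mean over all 20 tumours is 0.4%.

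The 2 wild-type sets were compared to see whether they could stand as 1 control. The WT_Dmt1 tumours stood higher than the WT_plain tumours at Slc38a8, an amino acid transporter gene on chromosome 8 (122008845 to 122024294), with 1.57 ± 0.41 (SD, n = 4) against -0.52 ± 0.75 (SD, n = 3), a difference of 2.09 (SE 0.35, limma adjusted p = 0.000498). Col2a1, a cartilage collagen gene on chromosome 15 (97811682 to 97826717), stood at 0.55 ± 0.23 against -1.33 ± 0.53 (difference 1.88, SE 0.22, limma adjusted p = 5.46e-05). Hdac1, a histone deacetylase gene on chromosome 4 (129199100 to 129214820), stood at 0.31 ± 0.23 against -1.58 ± 0.69 (difference 1.88, SE 0.26, limma adjusted p = 0.00013). These genes were chosen after their values were seen, and at each of them every WT_Dmt1 tumour stood above every WT_plain tumour. With the spots in the array patches left out the differences were 2.11 for Slc38a8, 1.17 for Col2a1 and 0.96 for Hdac1 (SE 0.35, 0.18 and 0.20). Other large differences did not hold, as at ENSMUST00000115249 on chromosome X, from 2.26 to 0.41 (limma adjusted p = 0.346), and 2900092C05Rik, from 2.12 to 0.13 (limma adjusted p = 0.606). Limma called 2947 of 9427 genes, 2505 higher and 442 lower in WT_Dmt1. It called 2443 with the patch spots left out and 1883 without WT_plain 2. Leaving out WT_plain 1 and 2 leaves 1 tumour in that set, so a count without them says little. The altered share was 2.76% ± 2.77 in WT_Dmt1 and 29.4% ± 10.58 in WT_plain, a difference of -26.65 percentage points (exact p = 0.0571, the smallest that 35 splits allow, two-sided), and breakpoints numbered 34.8 ± 42.4 against 553 ± 247.9 (difference -518.2, exact p = 0.0571). The lost share differed by -18.23 (exact p = 0.0571) and the gained share by -8.42 (exact p = 0.114). With the shared profile removed the altered share turned to 0.74 (exact p = 0.914) and the gained share to 1.23 (exact p = 0.571). The lost share then differed by -0.50 (exact p = 0.0571) and limma still called 2095 genes, 1446 higher and 649 lower. The sets lay on different slides and were scanned on different days, so set, slide and day could not be told apart.

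Across the 20 tumours the regions called lost most often were dense in genes. The counts and means given are those of the bins with the most tumours. On chromosome 11 from 115000001 to 122000000, with Bahcc1, Slc38a10 and Csnk1d, 19 of 20 tumours were called lost between 120000001 and 121000000, at a mean log2 ratio of -0.44. On chromosome 7 from 51000001 to 53000000, with the cell death gene Bax, the ferritin gene Ftl1 and the Hippo transcription factor gene Tead2, 19 tumours were called lost from 52000001 on, at a mean of -0.46. Chromosome 10 from 79000001 to 81000000, with Gpx4, which protects membranes from lipid peroxides, and the tumour suppressor Stk11, was called lost in 18 at -0.55, and chromosome 8 from 72000001 to 75000000, with Pde4c, Ell and Haus8, in 18 between 73000001 and 74000000, at -0.41. Chromosome 19 from 3000001 to 9000000, with Frmd8 and Pola2, and chromosome 2 from 164000001 to 168000000, with B4galt5 and Slc9a8, were each called lost in 17, in bins between 4000001 and 7000000 and from 167000001 on, at -0.39 and -0.37. In all, 180 of 2392 bins of 1 Mb were called lost in 9 or more tumours, the number that 10000 shifts of the profiles along the autosomes set for a family-wise p under 0.05, and the family-wise p of the top bin was 0.0001, the smallest the shifts can give. These bins held a mean of 24.5 named genes, against 8.87 over all bins, and their mean log2 ratio was -0.12 on scan day 1 and -0.37 on scan day 2. The count of 180 became 91 with normexp, 297 at a threshold of 0.1 and 53 in the tumours of scan day 1 alone.

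Regions called gained most often held few genes. On chromosome 15 from 13000001 to 25000000, a stretch whose leading entries are cDNAs without a gene symbol, 10 of 20 tumours were called gained in bins between 14000001 and 23000000, at a mean log2 ratio of 0.17. A region of vomeronasal receptor genes (Vmn2r84, Vmn2r86 and Vmn2r87) on chromosome 10 from 129000001 to 130000000 was also called gained in 10 at 0.17. Among regions called gained in 7 tumours was chromosome 5 from 55000001 to 63000000, with the protocadherin gene Pcdh7 (mean 0.14). In all, 45 bins were called gained in 7 or more tumours and held a mean of 1.98 named genes. This count ran from 26 without WT_plain 1 to 83 without WT_Dmt1 2, and was 1 at a threshold of 0.3 and 1 with normexp. With the profile shared by the arrays removed, an alternative chosen after seeing the data that would also remove any change common to most tumours, 0 bins were recurrently lost. The most often lost bin then had 2 tumours (family-wise permutation p = 0.137). A single bin was recurrently gained, the Skint cluster on chromosome 4 from 112000001 to 113000000, in the 3 WT_plain tumours (family-wise permutation p = 0.0041).

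**Figure D2:**
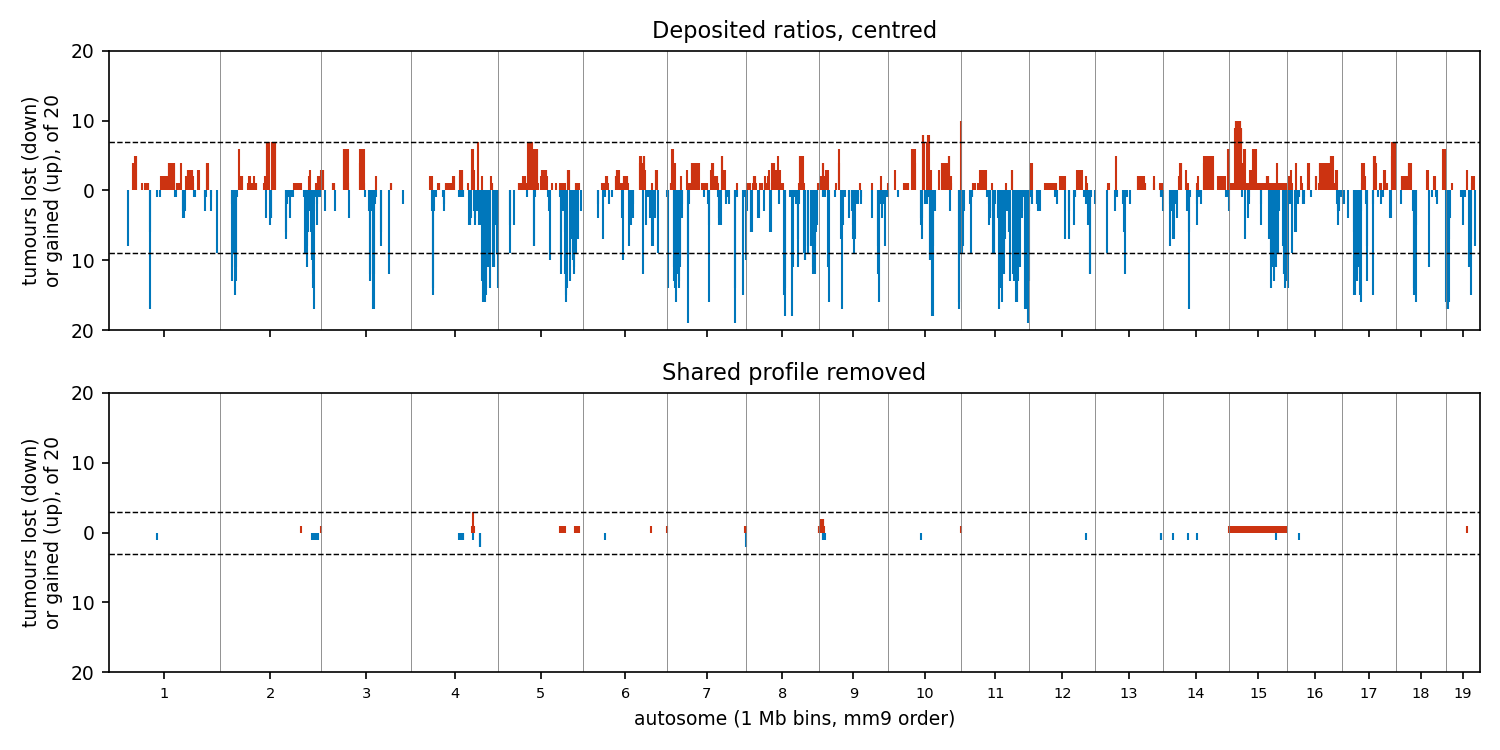
The horizontal axis is position along the autosomes in bins of 1 Mb and the vertical axis the number of the 20 tumours called gained (up) or lost (down), from the deposited ratios and with the shared profile removed; dashed lines mark the number needed for a family-wise p under 0.05. From the deposited ratios 180 bins pass for loss and 45 for gain; with the shared profile removed 0 and 1 do.

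Cdkn2a, Cdkn2b and Mtap, neighbours on chromosome 4 that are often deleted together in mesothelioma, were deeply lost in a single tumour. In WT_plain 2 a segment from 88357461 to 94074848 stood at -1.13 (SE 0.04 over 224 probes), while the other 19 tumours averaged 0.13 ± 0.08 (SD) and ran from -0.04 to 0.26. The probe means in that tumour were -1.76 at Cdkn2a, which encodes p16 and p19Arf, -1.15 at Cdkn2b, which encodes p15, and -1.19 at Mtap, a purine salvage enzyme gene. With the shared profile removed they were -1.71, -1.40 and -1.29, and no other gene of the list of mesothelioma tumour suppressors was then called lost in any tumour. From the deposited ratios more members were called lost. Stk11 was called lost in 18 of 20 tumours (mean -0.97 ± 0.34 SD), Setdb1, a histone methyltransferase gene, in 17 (-0.32), Trp53 in 16 (-0.46 ± 0.30), Rassf1 in 16 (-1.02, 1 probe), Sufu in 15 and Tsc2 in 15. Nf2, the Hippo regulator Merlin, was called lost in 9 (-0.24 ± 0.17), and Nf1, Bap1 and Pbrm1 in 7 each (-0.07, -0.03 and -0.15). Lats2 and Setd2 were called lost in 3 each, Rb1 and Ptch1 in 1 each, and Lats1, Tsc1 and Fbxw7 in none, while Cul1 was called gained in 1 and Cdkn2b in 2. Bap1, Stk11 and Cdkn2b had no probe of their own name and were read from probes between their neighbours.

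**Figure D3:**
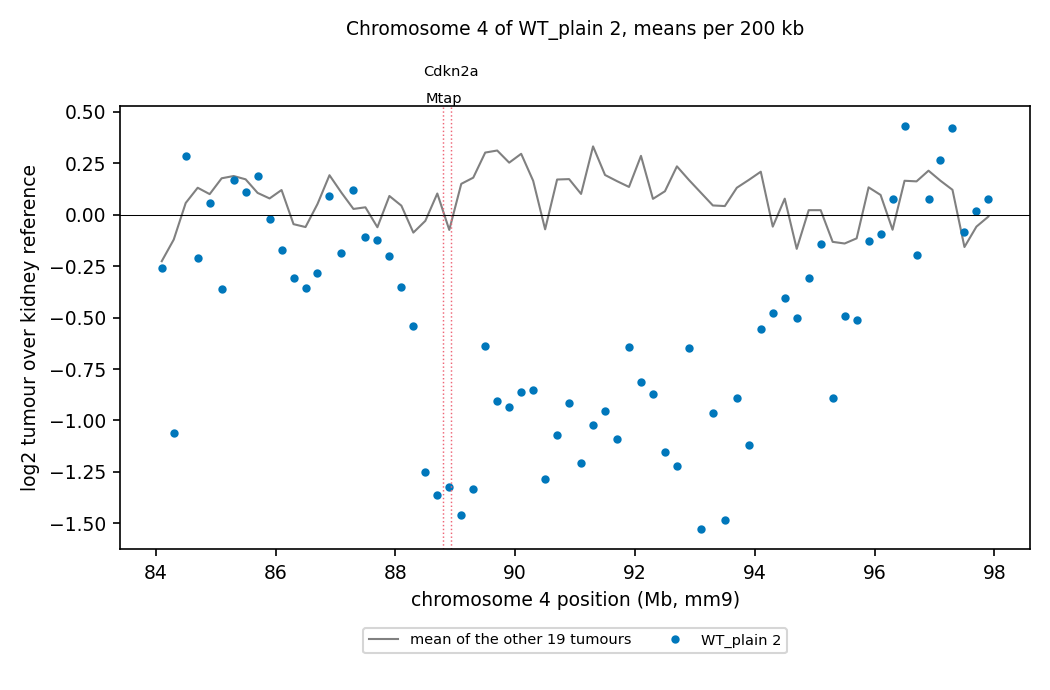
The horizontal axis is position on chromosome 4 in Mb and the vertical axis log2 of tumour over kidney in means of 200 kb; blue points are WT_plain 2, the grey line is the mean of the other 19 tumours and vertical lines mark Mtap and Cdkn2a. WT_plain 2 stands at -1.13 across the segment and the others average 0.13.

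Members of most lists fixed for this tissue and exposure were called lost more often than in shifted profiles, a comparison that leaves out that genes lie in gene-dense bins. Chromatin regulators were called lost in a mean of 6.86 tumours per member (29 members), against 1.46 when profiles were shifted, with Setdb1 in 17 tumours (-0.32) and Arid1a, Smarca4, Kmt2b and Dnmt1 in 16 each. Apoptosis genes reached 6.45 (22 members), with Bax in 19 (-1.11 ± 0.30 SD), Mcl1 and Bad in 17 and Bbc3, Casp9 and Diablo in 15. Tumour suppressors reached 5.82 (22 members) and iron handling genes 5.56 (41 members), with Ftl1 in 19 (-1.11), Gpx4 in 18 (-1.08 ± 0.31), Slc11a1 and Hjv in 17, Keap1 in 16 and Lcn2 in 15. Cell cycle brakes stood at 4.56 (Cdkn2d in 16, Cdkn1a in 12, Cdkn1b in 8, Rbl1 in 6), Hippo genes at 4.52 (Taok2 in 19, Tead2 and Ajuba in 17, Tead3 in 13), double-strand break repair genes at 3.91 (H2ax in 17 at -1.23 ± 0.34, Nhej1 in 17, Brca1 in 16, Blm in 15) and base excision repair genes at 3.83 (Nthl1 and Aptx in 15, Smug1 in 13). Oncogenes stood at 3.58 (Erbb3 and Terc in 17, Cdk4 in 16, Hras in 15) and mesothelial genes at 2.9 (Krt8 and Krt18 in 13, Msln and Upk3b in 10). The one-sided permutation p was 1.0e-04, the smallest the shifts can give, for the first 9 of these lists and the engineered genes and 2.0e-04 for mesothelial genes (adjusted p = 0.000233 and 0.000431). Fragile-site genes were called gained in 2.22 tumours per member against 0.88 (23 members), with Pcdh15 in 8 (0.18), Csmd3 and Ctnnd2 in 6 and Ctnna3 in 5, and copy-variable families in 1.67 (216 members), both at a permutation p of 1.0e-04. Over all 20277 named autosomal genes the means were 3.73 tumours for loss and 0.31 for gain. Against random lists of as many of these genes, drawn 10000 times, a test added after seeing the data, only chromatin regulators passed for loss (permutation p = 0.0021, adjusted p = 0.0196). Fragile-site genes and copy-variable families passed for gain (permutation p = 1.0e-04, adjusted p = 0.0014), though the draws take neighbouring members as independent. Antigen receptor loci passed for neither loss (0.17) nor gain (1.17, permutation p = 0.28) in either test. With the shared profile removed no list passed for loss or gain (lowest adjusted permutation p = 0.161). Between genotypes and wild type 0 of 56 tests of lists passed. Of the 52 pairs of list and contrast, 4 held a gene that limma called adjusted over the list alone, each with 1 gene, and over all genes it called 0 of them.

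Other segments stood apart in single tumours. WT_Dmt1 2 was gained along the whole of chromosome 15 (3114799 to 103216429, with the oncogene Myc), at 0.32 (SE 0.006 over 6658 probes) where the other 19 averaged -0.02 ± 0.05 (SD), and on chromosome 5 from 113164495 to 114577385 at 0.74 (SE 0.05). WT_Dmt1 1 stood at 0.40 (SE 0.09) on chromosome 7 from 151626013 to 152520747, which holds the cyclin gene Ccnd1, and at 1.23 (SE 0.17) over the kallikrein genes of the same chromosome from 51276046 to 51482589. The Ccnd1 stretch was not called from the deposited ratios, where its segmented value was 0.08. WT_plain 2 was lost on chromosome 9 from 9837924 to 14716464, with Amotl1, a Yap1-binding protein gene, and Mre11a, a break repair gene, at -0.51 (SE 0.04) against 0.11 ± 0.08 in the others. Of the focal segments with the most extreme means, most lay in stretches where the other tumours were low too, among them Dnttip1, Snx21 and Acot8 on chromosome 2 in WT_plain 2 (-1.73, others -0.84), Ticam1, Plin3 and Arrdc5 on chromosome 17 in WT_plain 3 (-1.61, others -0.91), Malat1 and Frmd8 on chromosome 19 in WT_plain 2 (-1.42, others -0.72) and Kmt2b on chromosome 7 in WT_plain 3 (-1.34, others -0.84). Cacna2d2, Rassf1 and Hyal3 stood at -1.33 in WT_plain 3, Sirt4, Pxn and Gcn1 at -1.33 in WT_plain 2, Pgpep1, Pde4c and Pik3r2 at -1.29 in WT_plain 2, and H2ax at -1.25 in WT_plain 1. Fam171a1 at the start of chromosome 2 stood at -1.28 in WT_plain 2 (SE 0.85 over 5 probes), where the others averaged -0.29.

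**Figure D4:**
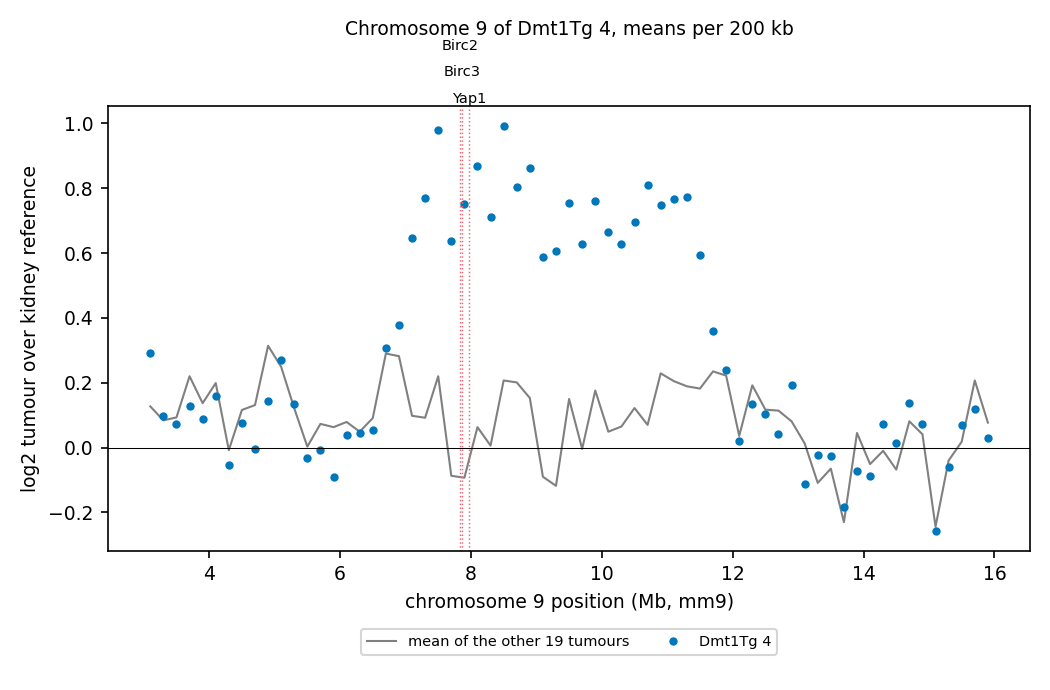
The horizontal axis is position on chromosome 9 in Mb and the vertical axis log2 of tumour over kidney in means of 200 kb; blue points are Dmt1Tg 4, the grey line is the mean of the other 19 tumours and vertical lines mark Yap1, Birc2 and Birc3. Dmt1Tg 4 stands at 0.74 across the segment and the others average 0.08.

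**Figure D5:**
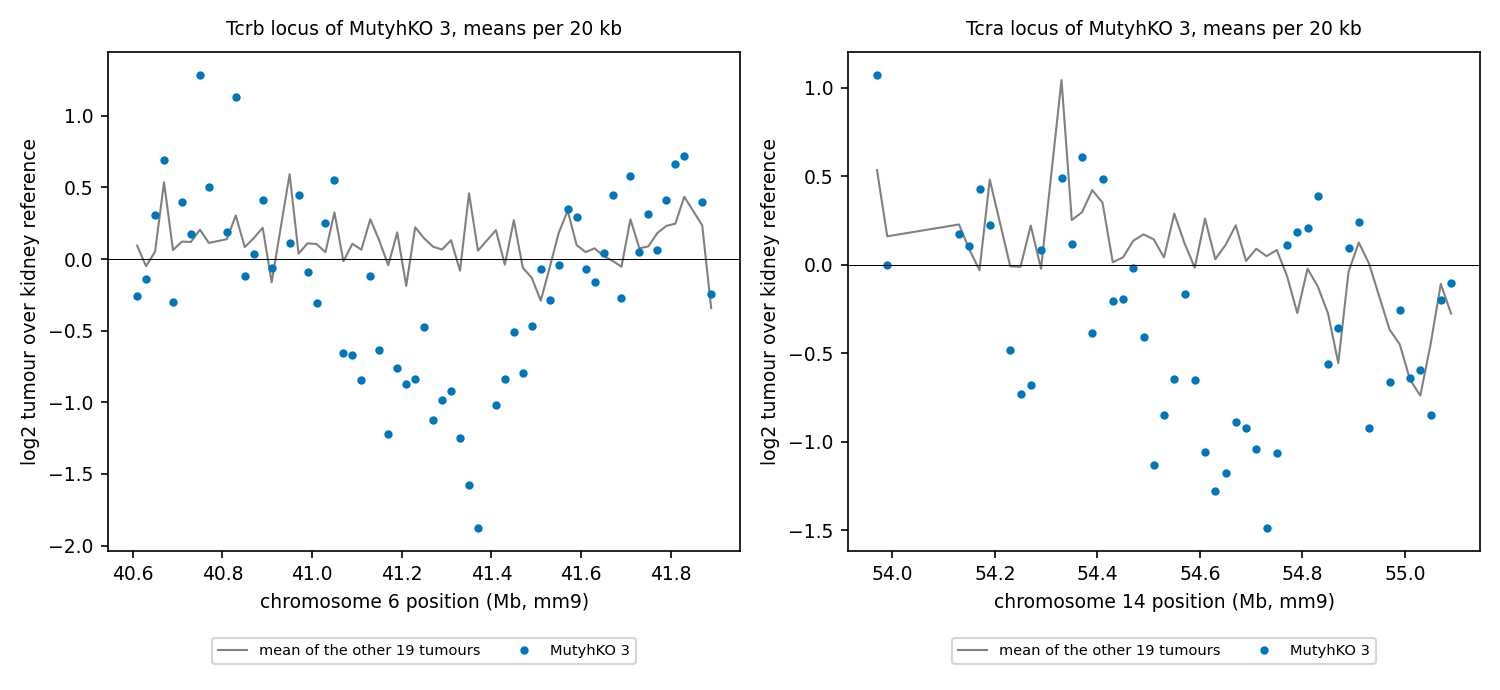
The horizontal axes are positions in Mb at the T-cell receptor beta locus on chromosome 6 and the alpha locus on chromosome 14, and the vertical axes log2 of tumour over kidney in means of 20 kb; blue points are MutyhKO 3 and the grey line the mean of the other 19 tumours. The lost parts stand at -0.90 and -1.06, and the others average 0.08 and 0.11.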

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

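The tests of this part were chosen after the results were seen, except the tests of array noise and of background at Y probes, whose predictions were written before.

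The first pattern is the loss of gene-dense regions in most tumours, and across the 12 tumours of scan day 2 the depth of the recurrently lost bins followed the slope of the ratio on genes per bin measured in bins past no recurrence threshold (r = 0.85, permutation p = 0.00056, adjusted p = 0.0015 over 8 relations, rho = 0.90, permutation p = 0.00026, r = 0.83 without the 2 farthest). On day 1 r was 0.97 over 8 tumours (permutation p = 0.00052, adjusted p = 0.0015, rho = 0.86, permutation p = 0.011, r = 0.92 without the 2 farthest), while the measure tried first, the share of gene-named probes, gave r = 0.60 on day 1 and 0.48 on day 2 (permutation p = 0.12 and 0.11, adjusted p = 0.16). Measured in bins called in no tumour, the slope on genes per bin gave r = 0.97 on day 1 and 0.78 on day 2 (permutation p = 0.0003 and 0.0035, adjusted p = 0.0015 and 0.007), and that on gene-named probes 0.40 and 0.18 (permutation p = 0.32 and 0.58, adjusted p = 0.37 and 0.58). Slope and depth came from the same arrays, and the lost bins are gene-dense bins picked from them. Any profile common to the arrays whose size differs between them would give such correlations. They therefore do not separate an array trend from other causes. Losses of DNA common to the tumours are argued against as the whole cause, since bins called in no tumour carried the same trend (rho = -0.56 across 1140 bins, which are not independent). More S-phase cells in the tumours would raise, not lower, the ratio of gene-dense bins that replicate early. The 245 bins densest in genes lay below 0 in 19 of 20 tumours, but this restates the pattern and is no separate test. An array trend on genome composition, whose size differs between arrays and scan days, is a candidate explanation that stays open, and whether some real losses lie under it was not tested.

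The second pattern is the low ratio at the T-cell receptor loci of MutyhKO 3. Array noise is argued against, because the lowest mean over 35 consecutive probes elsewhere on the array, outside the alpha and beta loci and with called segments included, was -0.42 and the beta locus stood at -1.01 with the shared profile removed. T cells in the sample, of 1 clone or of many, stay open. To give mean depths of -0.90 (beta) and -1.06 (alpha) in the deposited ratios, they would have to supply a large part of its DNA. That share was not estimated. The loss far from the joining segments had 0.717 of the depth of the near end, between the bound of 0.75 or more set for 1 clone and that of under 0.5 set for many, and a germline deletion was not tested. The gamma locus stood at 0.04 and the heavy chain, kappa and lambda immunoglobulin loci at 0.24, 0.20 and 0.29.

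The third pattern is a Y ratio between those of the other tumours. The Y median was -1.53 in WT_Dmt1 4 and -0.98 in WT_plain 3, where X stood at 0.73 and 0.67. In the 14 other tumours with low Y, X was 0.93 ± 0.07 (SD, 0.79 to 1.03) and the mean Y -2.76 (-3.53 to -1.2). The highest Y of these was that of WT_Dmt1 1, so WT_Dmt1 4 lay within their Y range. A mixture of DNA of male and female animals is a candidate explanation, since X lay 0.10 from the value a mixture gives in WT_plain 3 and 0.00 in WT_Dmt1 4, but Y loss with X gain in part of a male tumour gives the same X (0.67 and 0.73) and cannot be told apart from it. Background at Y probes also stays open there, with bright probes -0.36 and -0.93 from dim ones. These gaps were smaller than those of the 14 other tumours, which ran from -3.13 (Ogg1KO 1) to -1.59 (WT_plain 1). In WT_Dmt1 1, with a Y median of -1.2 and X of 0.86, bright Y probes lay -2.46 from dim ones. Tumours with a lower Y had gaps of that size too, so the measure cannot say whether background accounts for the value.

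Chromosome Y was outside the main measurement. In 4 tumours its median lay near 0, at -0.03 in MutyhKO 2, 0.04 in MutyhKO 3, 0.01 in Ogg1KO 3 and -0.06 in Mth1KO 2, and their X medians were -0.03, 0.06, 0.02 and 0.16.

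Single tumours passed the gap test in 13 of 90 groups checked, where chance gives about 1 in 20, the rate of its critical value. The test sets a gap against the range of the group, so a small gap can pass, as at Fbxw7, Lats2 and Rb1, and Cdkn2a, Cdkn2b and Mtap are 1 segment. WT_plain 2 stood at -1.13 at Cdkn2a, Cdkn2b and Mtap, the nearest other wild type at -0.02. WT_Dmt1 4 had 4.59% of the autosomes lost against 0.75% in the nearest, and WT_Dmt1 2 had 4.89% gained against 0.43%. Setdb1 stood at -0.39 in WT_Dmt1 4 (nearest -0.05), Tsc1 at -0.19 in WT_plain 3 (nearest -0.05), and Rassf1 at -0.78 in Dmt1Tg 3 (nearest -0.25). Nf1 stood at 0.01 in Dmt1Tg 1 (nearest -0.12), Fbxw7 at 0.02 in Dmt1Tg 3 (nearest 0.03), and Lats2 and Rb1 at 0.03 in WT_Dmt1 1. These gene values are segmented, but that of Nudt1 is a mean of 2 probes, -0.56 in Dmt1Tg 3 (nearest -0.03). Its probes stood at -0.01 and -1.11, and the low probe carries the name of another gene, Mrm2.

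The difference of Dmt1Tg from WT_Dmt1 was set against that of each knockout from WT_plain, by permutation within each contrast (12 tests, adjusted). Such shuffling tests whether neither contrast holds a difference, not whether the differences are equal. A difference in 1 contrast alone can therefore give a low p. All comparisons reuse the Dmt1Tg, WT_Dmt1 and WT_plain tumours, so they are not independent. For the altered share the differences were 19.79 percentage points apart for MutyhKO (adjusted permutation p = 0.0114), with 4 of 4 Dmt1Tg tumours above the WT_Dmt1 mean and 3 of 3 MutyhKO tumours below the WT_plain mean, 16.4 for Ogg1KO and 10.26 for Mth1KO (adjusted permutation p = 0.118 and 0.337). The gained share passed for none (adjusted permutation p = 0.337, 0.492 and 0.997). For the lost share they were 12.83 apart for MutyhKO, 12.04 for Ogg1KO and 10.3 for Mth1KO (adjusted permutation p = 0.00858, 0.00858 and 0.0417), and for breakpoints 582.2, 530.2 and 447.9 (adjusted permutation p = 0.0129, 0.0171 and 0.0417). In both measures 4 of 4 Dmt1Tg tumours lay above their wild-type mean and 3 of 3 tumours of each knockout below theirs, except the lost share in Mth1KO with 2 of 3. These comparisons lie on different scan days, and the WT_Dmt1 arrays were noisier than the Dmt1Tg arrays, which lowers the number of segments found. With the shared profile removed the permutation p ran from 0.15 to 0.794.

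Other splits of the same samples bear on the gene counts. For Dmt1Tg, MutyhKO, Ogg1KO and Mth1KO against wild type the real split gave 0 genes, so 100 of 100 splits gave as many by construction, so the splits are no test of chance here and it cannot be excluded. The highest other splits gave 1904, 1531, 1658 and 1712 genes and put WT_Dmt1 1 to 3 or WT_plain 1 to 3 on 1 side, beside Dmt1Tg 3 in the first, so they part the wild-type sets. Scan day and the patches on WT_plain 1 and 2 go with the sets and are not told apart from them by these splits. Against the wild-type set of the same scan day with the patches left out, limma called 0, 18, 3 and 4. For the 2 wild-type sets the real split gave 2947 genes and the highest of the other 34 gave 1668, with WT_Dmt1 4 placed beside WT_plain 1 to 3. So 1 of 35 splits was as large, the lowest share that 35 splits allow. With so few splits chance is not excluded, and scan day and slide cannot be told apart from the sets.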

How the results depend on the processing

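Planned tests are those of the thresholds, penalties, centring, normexp, dim probes, value table, matched wild types, blocks, probe minimums, bins, segmented values, single probes and left-out tumours; the rest were chosen after seeing the data. No difference between a genotype and the 7 wild-type tumours in share or breakpoints passed its test, so a turned sign here is the sign of a difference within the spread, and unless said the cause was not tested. The value table of the series and the correction for probe GC content turned no result they were run on and moved no count by a large amount, though gene counts need not be identical. A correction for GC content of the region around each probe was not run, because no genome of the build was given. The share of probes well above background in kidney (from 73.4%) limits what single genes can show.

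Set against the wild types of the same scan day, the altered share turned to 4.11 in Dmt1Tg, -12.28 in Ogg1KO and -6.14 in Mth1KO, the lost share to 5.1 in Dmt1Tg, -7.73 in MutyhKO, -6.94 in Ogg1KO and -5.2 in Mth1KO, the gained share to -0.94 in Mth1KO, and breakpoints to -294 in MutyhKO, -242 in Ogg1KO and -159.7 in Mth1KO. Genes called became 358 in MutyhKO, 250 in Ogg1KO and 249 in Mth1KO, and 403, 317 and 299 on autosomes alone, and scan cohort as a term in the fit gave the same counts. With spots in array patches left out as well they were 18, 3 and 4, so the patches on WT_plain 1 and 2 account for most of them. With the patch spots kept and the shared profile removed they were 63, 8 and 7, with 2 in Dmt1Tg (Ndufv2, a gene of mitochondrial complex I, and Nkain1). There the largest difference, 2900092C05Rik, stayed at 1.70, 2.04 and 1.88 and lost its call (limma adjusted p = 0.0651, 0.0731 and 0.064).

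With the shared profile removed the altered share turned to -1.0 in Ogg1KO, -1.0 in Mth1KO and 0.74 between the wild-type sets. The lost share turned to -0.16 in MutyhKO, -0.20 in Ogg1KO and -0.19 in Mth1KO, the gained share to -0.82 in Mth1KO and 1.23 between the wild-type sets, and breakpoints to -3.25 in Dmt1Tg, -2.33 in MutyhKO, -4.33 in Ogg1KO and -3.33 in Mth1KO. Recurrently lost bins became 0 and gained bins 1, and 0 and 0 with copy-variable families left out too; recurrently lost lists became 0 and gained lists 0. Against random lists of genes in place of shifts 1 list was lost and 2 were gained. Genes called in Dmt1Tg became 1, and 1 on autosomes alone, each time Ndufv2 on chromosome 17 (difference 0.48, SE 0.07). With the matched wild types and the shared profile removed together, the altered share was -1.25 in Dmt1Tg, -0.55 in MutyhKO, -0.58 in Ogg1KO and -0.58 in Mth1KO, the lost share -0.44 in MutyhKO, -0.48 in Ogg1KO and -0.47 in Mth1KO, the gained share -0.11 in Mth1KO, and breakpoints 1.25 in Dmt1Tg, -8.33 in MutyhKO, -10.3 in Ogg1KO and -9.33 in Mth1KO.

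With normexp the altered share turned to -2.2 in Ogg1KO and -2.1 in Mth1KO, the lost share to -2.13 in MutyhKO, -1.26 in Ogg1KO and -1.34 in Mth1KO, the gained share to -0.75 in Mth1KO and 0.46 between the wild-type sets, and breakpoints to -15.8 in Dmt1Tg and -3.95 in Ogg1KO. Recurrently lost bins became 91, gained bins 1 and gained lists 1. At a threshold of 0.1 the altered share turned to 11.47 in MutyhKO and the gained share to 3.46 in MutyhKO and 6.04 in Ogg1KO, with 297 lost and 121 gained bins. At 0.3 the gained share turned to -0.36 in Mth1KO and breakpoints to -60.8 in MutyhKO, with 1 gained bin. A penalty of 20 turned the gained share in Ogg1KO to 0.71, and 80 turned breakpoints to -23.7 in Dmt1Tg and -5.76 in MutyhKO. Centring on the mode turned the altered share in MutyhKO to 0.92. Without dim probes it was 0.28, breakpoints were -8.89 in Dmt1Tg and -22.8 in MutyhKO, 79 bins were gained, and the Mth1KO 1 segment on chromosome 4 from 111718181 turned to 0.34. Leaving out spots in array patches turned breakpoints in MutyhKO to -34.0 and gave 74 gained bins. Without the 2 tumours with patches the altered share in MutyhKO was 4.45, the lost share in Dmt1Tg 1.4, the gained share in Ogg1KO 0.26, and the genes between the wild-type sets 600. That count of genes rested on WT_plain 3 alone against WT_Dmt1, so it has no spread within WT_plain and says little. Tumours of scan day 1 alone gave 53 lost and 0 gained bins, and those of day 2 alone 80 gained bins.

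Genes between the wild-type sets numbered 1547 with at least 6 probes, 6078 with at least 1 probe and 5300 on segmented values, and 1195 of the 1 Mb bins passed. With at least 6 probes limma called 1 gene in Dmt1Tg, Arih1. The single probes of Slc11a2 turned to -0.04 and -0.28, of Mutyh to 0.17 and of Nudt1 to -0.06.

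Replicate numbers were used as a block with the matched wild types. Same-numbered tumours did not deviate together (correlations -0.13 to 0.11), so the values gave no sign of pairs. This does not exclude that the numbers mark a pairing. Under the replicate block the differences equal those against the matched wild types, 4.11, -12.28 and -6.14 for altered, 5.1, -7.73, -6.94 and -5.2 for lost, -0.94 for gained and -294, -242 and -159.7 for breakpoints. Limma then called 0 genes in each contrast (1096, 1236, 1016 and 1118 at an unadjusted p under 0.05), and 0 with slide as a random block. With slide as a fixed block it called 0 in the 3 knockouts, but WT_plain shared a slide only with MutyhKO 1. All 3 contrasts then passed through that 1 tumour, so these counts say little. This block was not run for Dmt1Tg, whose slide holds 1 group. The same matched tumours fitted with no replicate block gave 4 genes in Dmt1Tg, Camk2a, Dnah17, Ndufv2 and Pak6, and 0 in the others. The block changed no other call.

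Leaving out 1 tumour at a time, the altered difference ran from -9.61 to -3.72 in Dmt1Tg, from -2.76 to 3.13 in MutyhKO, from -1.01 to 7.19 in Ogg1KO and from 3.69 to 15.05 in Mth1KO. It turned in MutyhKO without WT_plain 1, WT_plain 2, WT_plain 3 or MutyhKO 3 (0.05, 3.13, 3.08 and 0.76) and in Ogg1KO without Ogg1KO 2 (-1.01). The lost difference ran from -4.24 to -0.34, from 1.15 to 5.06, from 1.94 to 5.85 and from 2.53 to 9.2 in the same order, and the gained difference from -5.42 to -2.85, from -3.96 to -1.39, from -3.76 to 1.64 (turned without WT_plain 2, WT_plain 3, Ogg1KO 1 or Ogg1KO 3) and from 1.16 to 5.85. Breakpoints ran from 24.5 to 149, from -39.5 to 85 (turned without any WT_Dmt1 tumour, MutyhKO 1 or MutyhKO 2), from -9.86 to 147.6 (turned without Ogg1KO 1) and from 75.6 to 219.3. Recurrently lost bins ran from 180 to 202 and gained bins from 26 (without WT_plain 1) to 83 (without WT_Dmt1 2), while list tests stayed at 0, lost lists at 11 and gained lists at 2. Genes called stayed at 0 in Dmt1Tg and ran from 0 to 28 in MutyhKO, with 28 without MutyhKO 1 (4 on autosomes alone, since the 2 tumours left have X and Y medians near 0) and 1 each without WT_Dmt1 1 (Slc34a1), WT_Dmt1 3 (Rftn2) or Ogg1KO 1. They ran from 0 to 1 in Ogg1KO (without Ogg1KO 1) and Mth1KO (without Mth1KO 1), and from 1883 (without WT_plain 2) to 2996 between the wild-type sets.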

Other observations

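The values of this part were chosen after they were seen and have no test of their own.

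The stretch of chromosome 14 that holds Slc25a37, Entpd4 and Loxl2 (69876584 to 70090608, 23 probes) took low, middle and high values across genotypes. It stood at -1.22 in WT_plain 1, -1.30 in WT_plain 2, -1.08 in MutyhKO 2, -1.23 in Mth1KO 2 and -1.23 in Mth1KO 3, and at 0.83 in MutyhKO 3, 0.73 in Ogg1KO 1 and 0.57 in Ogg1KO 2. With the shared profile removed these were -0.92, -1.0, -0.86, -0.96 and -0.97, and 1.12, 1.02 and 0.90. The Skint genes of chromosome 4 were high in the WT_plain tumours, at 0.71 in WT_plain 1 (111758445 to 113235586), 0.60 in WT_plain 2 (111786417 to 113251939) and 1.28 in WT_plain 3 (111742887 to 112091879). A low value there in Mth1KO 1, -0.45 (111718181 to 112202894), had a segmented value of 0.03 in the deposited ratios and turned to 0.34 without dim probes. In 14 tumours X stood at a mean of 0.93 and Y at -2.76 over kidney, the ratios of a female tumour over a male kidney, and read so the kidney on those arrays was not from the animal with the tumour.

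The start of chromosome 9 was altered in 3 tumours, with Yap1 inside the segment in 2 of them. Dmt1Tg 4 stood at 0.74 from 6969858 to 11562155, WT_Dmt1 1 at 0.26 (SE 0.02 over 646 probes) from 3046525 to 13490957, where the other 19 averaged 0.11 ± 0.10 (SD), and WT_plain 2, in a segment without Yap1, at -0.51 from 9837924 to 14716464. Other segments in WT_plain 2, the tumour with the Cdkn2a loss, were a low stretch of chromosome 13 from 117165113 to 118922925 at -0.50 (SE 0.05) and of chromosome 2 from 163546347 to 174684072 at -0.67 (SE 0.03), where the other 19 averaged -0.12 ± 0.12. WT_Dmt1 2 was also high on chromosome 5 from 114585819 to 121800152 at 0.35 and from 139696918 to 146728199 at 0.31.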
